A study of Homo sapiens with 4 samples.

How the data were processed

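RNA-seq was carried out on human primary monocytes cultured for 24 hours with or without IFN-γ, with 2 libraries per group. Per the labels, RNA was extracted with a QIAGEN kit and libraries followed the standard Illumina protocol; strand and read length are not given in the sources used here. The authors deposited FPKM, fragments scaled by transcript length and library size, for 23284 rows of RefSeq genes. Per the submitters' processing notes, CASAVA 1.7, TopHat and Cufflinks were used with genome build hg19, and the versions of the other tools are not given in the sources used here. Whether the FPKM were also scaled across libraries is not stated. The authors deposited beside each FPKM a text flag for the state of its estimate. Coordinates are those of the deposited table (hg19), whose intervals can span several overlapping genes.

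FPKM are not counts, so no count model was used and no absolute depth can be had from them. Among genes below 0.05 FPKM, ratios between libraries of the same replicate number pile up at single values, since each gene then holds only a few fragments. The most common bin of 0.04 log2 units held 20.35% of such genes for the replicate 2 pair, at a ratio IFNg- over IFNg+ of 0.88, and 5.62% for the replicate 1 pair, at 0.71. It held 2.32% to 2.73% for pairs of different numbers. This gives the relative worth of a fragment within a replicate number only, so depth is unknown and no interval or floor is given. Libraries of one number may thus have been handled alike, and each number holds 1 library of each group.

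The symbols of 27 of 28 rows that a spreadsheet had turned into dates were restored from their RefSeq accessions. Where a symbol had several rows, the highest was kept. B2M, FN1 and FTL were listed at 0 FPKM in at least 1 library under a flag for too much data, although monocytes express them, so they were not tested and only their values are given (FTL was at 0 in all 4). The 1603 rows of small RNAs were left out because FPKM of genes shorter than a fragment is unstable, as were the genes XIST and TSIX and those of the Y chromosome. Genes with a mean of at least 1 FPKM over the 4 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend, two-sided, Benjamini-Hochberg), with no term for the replicate number because the labels do not tie it to a donor. The call was an adjusted p under 0.05. Adjusted p-values of genes below are from this fit. The labels speak of donors but do not say that replicates came from separate donors or cultures, so p-values measure the spread between these libraries, which may be technical.

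34 gene lists, with each gene in 1 list only, were fixed from textbook knowledge before the data were examined, among them markers of 6 other blood cell types, as were the design, the rule for named genes and all alternatives but 1. The 28 lists with at least 5 tested members were tested with camera in limma with a preset correlation of 0.01 between genes, Benjamini-Hochberg adjusted over the lists. With a correlation estimated from the data, 0 of the 20 past lists held, and that adjusted p is given beside each call. In that form, camera rests on the few residual degrees of freedom that 4 libraries leave, so it could hardly pass a list. The complement list, with an estimated correlation of -0.083, went from an unadjusted camera p of 0.000172 to 0.0578. For that list, a lost call thus cannot by itself be put down to correlated genes. The list of type I interferon-stimulated antiviral genes had an estimated correlation of 0.837 and went from an unadjusted camera p of 3.64e-05 to 0.478. There, correlated genes and few degrees of freedom were not told apart. The directional test fry, which does not compare a list with other genes, passed 15 lists, and its mixed form 24. Named were the 12 largest rises and 12 largest falls among non-overlapping changed genes, in each list up to 4 changed members with the largest change and up to 2 with the highest expression that did not pass, and a few genes fixed beforehand, among them IRF1, IFNGR1, IFNGR2, MAF, ACTB and GAPDH. Where a list had 5 or fewer members of a kind, the others of that kind were taken after their values were seen. Not every gene so taken is named in the text. Genes whose presence differs between people by haplotype are not named.

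The fit was tested on 20 simulated data sets of 9966 genes with this design, 200 of them changed. It recovered 2% of 2-fold and 67.4% of 4-fold changes, with 5.8% false calls and 0 of the wrong sign. The data gave 1733 calls, far more than 200, which makes the adjusted threshold less strict than in simulation. The recovered shares thus do not carry over to the data. Genes were simulated as independent, and lists were judged at an unadjusted camera p under 0.05. A shifted list passed in 20 of 20 simulations and an unchanged list in 0, which does not test false list calls among correlated genes. Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, rescaling each library to the same sum (TPM, where the filter then kept 11471 genes), quantile normalization, alignment of medians, eBayes without trend or robust, the replicate number as a block, summed rows of a symbol, small RNA genes kept, limma treat against a 1.5-fold change, camera with an estimated correlation, fry, and each library left out in turn. A fit without 1 library leaves a group of 1 library and fewer degrees of freedom, so a call lost there need not mean a smaller change. Leaving out the 6 genes with a failed-fit flag was added after seeing the data. Transcript lengths for 1 check came from the GENCODE transcripts supplied with the reference, matched by current or older symbol. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.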

Results

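RNA from human primary monocytes, blood phagocytes isolated from mononuclear cells of healthy donors, was sequenced after 24 hours of culture with or without interferon-γ (IFN-γ), the cytokine by which T and NK cells activate macrophages. There were 2 libraries with IFN-γ (IFNg+ replicates 1 and 2) and 2 without (IFNg- replicates 1 and 2). The deposited values were FPKM per gene, and the depth behind them is unknown. FPKM summed over all genes except those of small RNAs to 315568 and 319519 in the IFNg- libraries and to 401619 and 395582 in the IFNg+ libraries. Between 9950 and 10176 genes reached 1 FPKM in a library. Values are given below as mean ± SD of 2 libraries per group, and fold changes as log2 ± SE on the log2(FPKM + 1) scale, with IFN-γ minus without, which understates the change of low genes.

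The comparison asked how the monocyte transcriptome responds to IFN-γ. The T-cell-attracting chemokine CXCL9 rose from 0.885 ± 0.141 to 826 ± 148 FPKM, and IDO1, the tryptophan-degrading enzyme, from 0.820 ± 0.194 to 737 ± 48.5 FPKM. The antimicrobial GTPase GBP5 rose from 1.46 ± 0.299 to 618 ± 25.8 FPKM, and SOCS1, the feedback inhibitor of JAK-STAT signalling, from 0.287 ± 0.0637 to 87.4 ± 18.5 FPKM. In the other direction, the adhesive glycoprotein THBS1 fell from 345.1 ± 256 to 0.735 ± 0.262 FPKM and the selenium carrier SEPP1 fell from 195 ± 109 to 0.124 ± 0.0214 FPKM. The complement receptor VSIG4, a marker of resident macrophages, fell from 319 ± 9.14 to 8.35 ± 6.20 FPKM. Among 10223 genes tested with limma, 1733 (17%) changed at an adjusted p under 0.05. Of these, 1019 were higher and 714 lower with IFN-γ. At least a 2-fold change was seen for 700 higher and 429 lower genes, and at least a 16-fold change for 47 and 16.

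**Figure D1:**
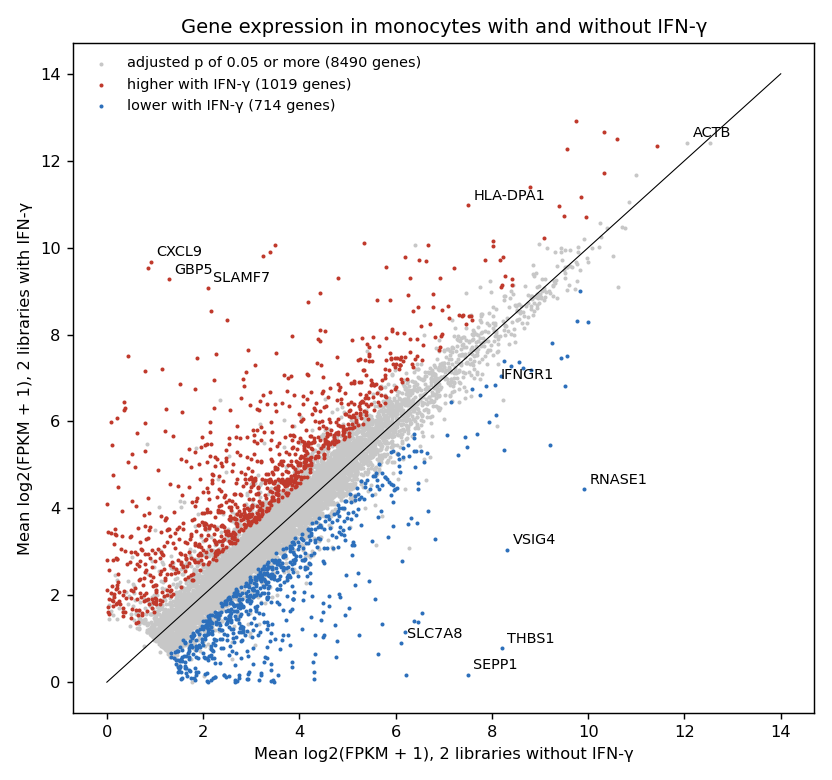
Mean log2(FPKM + 1) of the 2 libraries without IFN-γ (x axis) and of the 2 with IFN-γ (y axis) for the 10223 genes tested, each point a gene. The 1019 higher genes are red, the 714 lower genes blue and the rest grey, with equal expression on the diagonal.

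The spread between groups exceeded that between replicates. Pearson's r across genes was 0.977 between the IFNg- replicates and 0.972 between the IFNg+ replicates, and 0.865 to 0.886 between libraries of different groups (genes are not independent replicates). The SD of the log2 fold change was 0.862, against 0.362 and 0.433 for the log2 difference between replicates. The groups did not overlap for 64.5% of genes, where chance gives 33.3%. Small RNA genes, left out of the test, took 13.72% and 13.34% of FPKM in the replicate 1 libraries and 7.3% and 8.92% in the replicate 2 libraries, and each number has 1 library of each group. Within the replicate numbers, the log2 differences between the groups correlated across genes (Pearson's r = 0.889). The count of changed genes was 600 without IFNg- replicate 1 and 764 without IFNg- replicate 2. The share of higher genes among the calls was 58.8% with the deposited FPKM. It was 25.1% after rescaling to TPM. That step moved the median log2 fold change of all genes from 0.041 to -0.309 and made the pseudocount of 1 smaller beside the values. The share was 49.3% after quantile normalization and 48.1% after aligning the medians, which both centre the libraries and so pull the balance towards even. The balance of rises and falls thus depended on the scaling.

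The 12 largest rises also included ANKRD22 (log2 fold change 7.07 ± 0.15, adjusted p = 0.000312) and SLAMF7, a self-ligand receptor of leukocytes (6.98 ± 0.24, adjusted p = 0.00076). The chemokines CXCL10 and CCL8 rose by 6.58 and 6.38, and the GTPases GBP1 and GBP4 by 6.56 and 6.07. SERPING1, the C1 inhibitor of complement, rose by 6.38, and FAM26F, a predicted channel protein, by 6.50. The fold changes of the leading genes were 8.77 ± 0.19 for CXCL9 (hg19 chromosome 4, 76922622 to 76928641), 8.67 ± 0.16 for IDO1 (chromosome 8, 39771327 to 39786309) and 7.98 ± 0.16 for GBP5 (chromosome 1, 89724633 to 89738544), each with an adjusted p of 0.000312. SOCS1 rose by 6.09 ± 0.19 (adjusted p = 0.000624). The values of guanylate-binding proteins are uncertain, since similar copies can share reads.

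Among the 12 largest falls, THBS1 (hg19 chromosome 15, 39873279 to 39889668) had a log2 fold change of -7.42 ± 0.56 (adjusted p = 0.00349) and SEPP1 (chromosome 5, 42756919 to 42812024, an interval that holds 2 genes of the table) one of -7.33 ± 0.40 (adjusted p = 0.00164). The chemokine precursor PPBP fell from 82.2 ± 53.5 to 0.115 ± 0.0954 FPKM (adjusted p = 0.00375). The secreted ribonuclease RNASE1 fell from 1054 ± 601 to 30.6 ± 32.3 FPKM (adjusted p = 0.0243). The log2 fold change was -5.22 for the amino acid transporter SLC7A8, -5.07 for the adaptor PID1, -5.03 for the integrin subunit ITGB5 and -4.997 for the actin regulator MTSS1. It was -4.97 for the RANK receptor TNFRSF11A, -4.95 for the lysophospholipid receptor GPR34 and -4.38 for the heparan sulphate proteoglycan SDC2. The call of RNASE1 was lost without IFNg- replicate 1 and without IFNg- replicate 2. Its log2 fold change there was -6.09 and -4.85, against -5.47 with all libraries. Across the alternatives, adjusted p of RNASE1 ranged from 0.00273 to 0.0812.

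**Figure D2:**
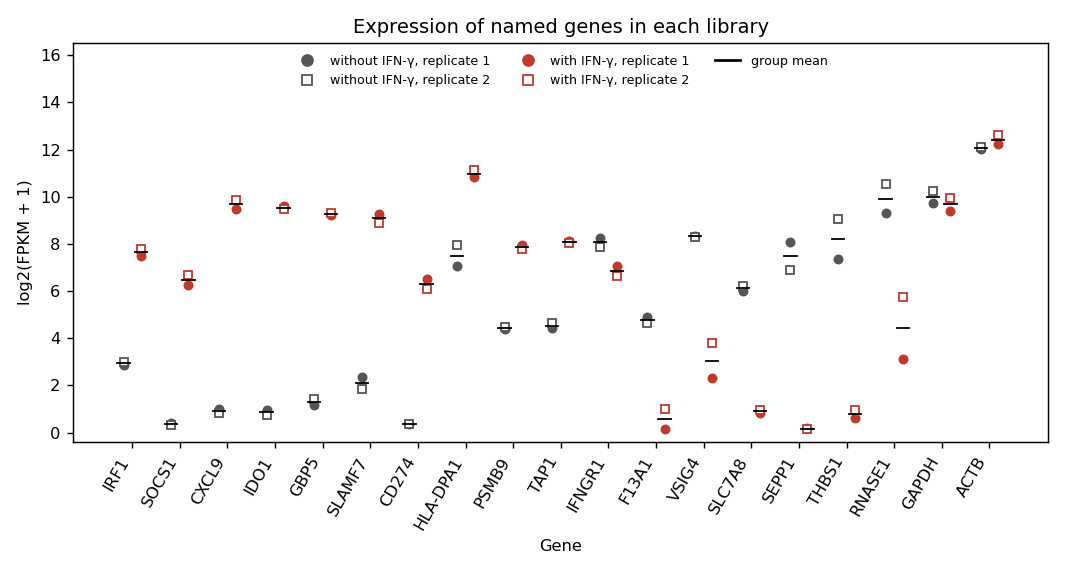
Expression of named genes as log2(FPKM + 1) in each of the 4 libraries, grey without and red with IFN-γ, circles for replicate 1 and squares for replicate 2, with a line at each group mean. The log2 fold change of ACTB, 0.349 here, was -0.009 after rescaling to TPM and -0.667 after quantile normalization, and neither ACTB nor GAPDH passed the test.

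IFN-γ signalling components were mostly higher. Of 17 members tested, 9 rose, 1 fell and 7 did not pass the test (limma camera adjusted p = 3.14e-05, 1.47e-07 to 0.357 over the alternatives, and adjusted p = 0.357 with an estimated correlation; 13 higher and 2 lower adjusted over the list alone). The kinase JAK2 rose from 10.4 ± 0.553 to 75.3 ± 14.8 FPKM (log2 fold change 2.73 ± 0.19, adjusted p = 0.00276), and the feedback inhibitor SOCS3 from 1.34 ± 0.0923 to 13.02 ± 3.99 FPKM. The ligand-binding receptor chain IFNGR1 fell from 269.8 ± 48.3 to 115 ± 21.8 FPKM (log2 fold change -1.22 ± 0.22, adjusted p = 0.0275). The second chain IFNGR2 was at 84.3 ± 2.59 FPKM without and 115 ± 11.1 FPKM with IFN-γ and did not pass (adjusted p = 0.129), nor did the phosphatase PTPN6 (log2 fold change 0.53). IFNGR1 was not past the threshold without IFNg- replicate 1 (adjusted p = 0.131), without IFNg- replicate 2 (adjusted p = 0.0635) and without IFNg+ replicate 2 (adjusted p = 0.0527). The adjusted p over all alternatives of IFNGR1 ranged from 0.013 to 0.196.

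Of 32 guanylate-binding proteins and classical IFN-γ targets tested, 31 rose (limma camera adjusted p = 3.21e-25, 1.63e-38 to 0.348 over the alternatives, and adjusted p = 0.348 with an estimated correlation; 32 higher and 0 lower adjusted over the list alone). IRF1, the transcription factor that drives many of these genes, rose from 6.63 ± 0.533 to 200.2 ± 27.6 FPKM (log2 fold change 4.72 ± 0.17, adjusted p = 0.000814). The exception was the myeloid factor IRF8, at 57.4 ± 14.8 FPKM without and 88.7 ± 11.2 FPKM with IFN-γ (adjusted p = 0.134).

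Antigen presentation genes rose in both classes. Of 18 MHC class II genes tested, 14 rose, 1 fell and 3 did not pass (limma camera adjusted p = 4.73e-07, 4.6e-12 to 0.348 over the alternatives, and adjusted p = 0.348 with an estimated correlation; 14 higher and 1 lower adjusted over the list alone). HLA-DPA1 rose from 189 ± 82.3 to 2026 ± 289 FPKM, HLA-DQA1 from 29.7 ± 18.5 to 637 ± 89.7 FPKM and HLA-DOA from 1.11 ± 0.245 to 28.9 ± 6.79 FPKM, and HLA-DQB1 by 3.22 on the log2 scale. The lysosomal protease LGMN fell from 737 ± 56.5 to 117 ± 46.4 FPKM (adjusted p = 0.00896). The ubiquitin ligase MARCHF1 and the promoter factors RFXANK and RFXAP did not pass, at log2 fold changes of 0.30, 0.20 and -0.38. Of 20 MHC class I and immunoproteasome genes, 13 rose and 7 did not pass (limma camera adjusted p = 4.98e-09, 9.56e-14 to 0.349 over the alternatives, and adjusted p = 0.349 with an estimated correlation; 16 higher and 0 lower adjusted over the list alone). The peptide transporter TAP1 rose from 22.3 ± 2.67 to 269 ± 14.2 FPKM, the proteasome subunit PSMB9 from 20.6 ± 1.17 to 231 ± 19.6 FPKM and the proteasome activator PSME2 from 99.5 ± 22.2 to 842 ± 184 FPKM, while the transactivator NLRC5 rose by 2.72 on the log2 scale. PDIA3 and CALR, chaperones of peptide loading, did not pass (log2 fold changes 0.57 and -0.005). Class I and class II HLA values are uncertain because their reads are shared between paralogs and depend on how a donor's alleles match the reference. B2M, the light chain of class I molecules, was listed at 6191.21 and 6522.49 FPKM in the IFNg- libraries and at 0 in both IFNg+ libraries. That 0 came with the flag for too much data, a failed estimate and no sign of absence, so B2M was not tested. RFXAP passed the test after rescaling to TPM (adjusted p = 0.0381). PDIA3 passed the test without the variance trend (adjusted p = 0.0477). Over all alternatives, the adjusted p of PDIA3 and RFXAP ranged from 0.0381 to 1.

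Among 37 type I interferon-stimulated antiviral genes tested, 15 rose, 0 fell and 22 did not pass. The list was past (limma camera adjusted p = 0.000145, 8.47e-10 to 0.592 over the alternatives, and adjusted p = 0.592 with an estimated correlation). Adjusted over the list alone, 18 members were higher and 0 lower. With the directional fry test, which compares no other genes, the list was not past (adjusted p = 0.17). IFI27 rose from 3.78 ± 1.53 to 124 ± 17.9 FPKM, the exonuclease ISG20 from 3.36 ± 2.72 to 51.3 ± 23.0 FPKM and the antiviral enzyme RSAD2 from 18.6 ± 11.3 to 137 ± 16.49 FPKM. IFITM1, which blocks viral entry, rose by 3.37 on the log2 scale (adjusted p = 0.0454). IFI6 was at 616 ± 48.0 FPKM without and 483 ± 149 FPKM with IFN-γ (adjusted p = 0.352), and IFITM3 had a log2 fold change of 1.27 (adjusted p = 0.142). IFITM1 lost the call without IFNg- replicate 1 (adjusted p = 0.117), without IFNg+ replicate 2 (adjusted p = 0.0761) and after quantile normalization (adjusted p = 0.0597). Across the alternatives, adjusted p of IFITM1 ranged from 0.00541 to 0.12.

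Alternative-activation and scavenger genes fell on balance. Of 31 tested, 14 fell, 4 rose and 13 did not pass (limma camera adjusted p = 0.00197, 0.000165 to 0.348 over the alternatives, and adjusted p = 0.348 with an estimated correlation; 5 higher and 17 lower adjusted over the list alone). After rescaling to TPM the list was no longer past, with a median log2 fold change of -1.04 (adjusted p = 0.227). Besides SEPP1 and VSIG4, the coagulation factor subunit F13A1 fell from 26.4 ± 3.46 to 0.559 ± 0.619 FPKM. The transglutaminase TGM2 rose from 1.33 ± 0.184 to 55.03 ± 12.8 FPKM. IL1RN, the antagonist of the IL-1 receptor, and the lectin receptors CLEC7A and CD209 also rose, by 3.50, 0.86 and 0.82 on the log2 scale. The transcription factor MAF was at 24.996 ± 13.3 FPKM without and 8.86 ± 2.71 FPKM with IFN-γ, with a log2 fold change of -1.32 ± 0.42 that did not pass the test (adjusted p = 0.0967). MS4A6A and the scavenger receptor MSR1 did not pass (log2 fold changes 0.50 and 0.42). CD209 did not pass without IFNg- replicate 1 (adjusted p = 0.0657), without IFNg- replicate 2 (adjusted p = 0.168), without IFNg+ replicate 1 (adjusted p = 0.127), without IFNg+ replicate 2 (adjusted p = 0.101), after rescaling to TPM (adjusted p = 0.121), after quantile normalization (adjusted p = 0.0754) and after median alignment (adjusted p = 0.0647). CLEC7A did not pass without IFNg- replicate 1 (adjusted p = 0.122), without IFNg- replicate 2 (adjusted p = 0.129), without IFNg+ replicate 1 (adjusted p = 0.06), after rescaling to TPM (adjusted p = 0.0621) and after quantile normalization (adjusted p = 0.09). MAF passed the test without IFNg- replicate 2 (adjusted p = 0.043) and after rescaling to TPM (adjusted p = 0.0452). Over all alternatives, the adjusted p of these genes ranged from 0.0191 to 0.809. The fibronectin gene FN1 was listed at 0 in both IFNg- libraries under the flag for too much data, so that 0 is a failed estimate and no sign of absence. It was at 16.2 and 30.7 FPKM in the IFNg+ libraries. The listed values thus do not show a rise, since the flag stands for too many fragments and not too few. No size of change can be given, and FN1 was not tested.

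**Figure D3:**
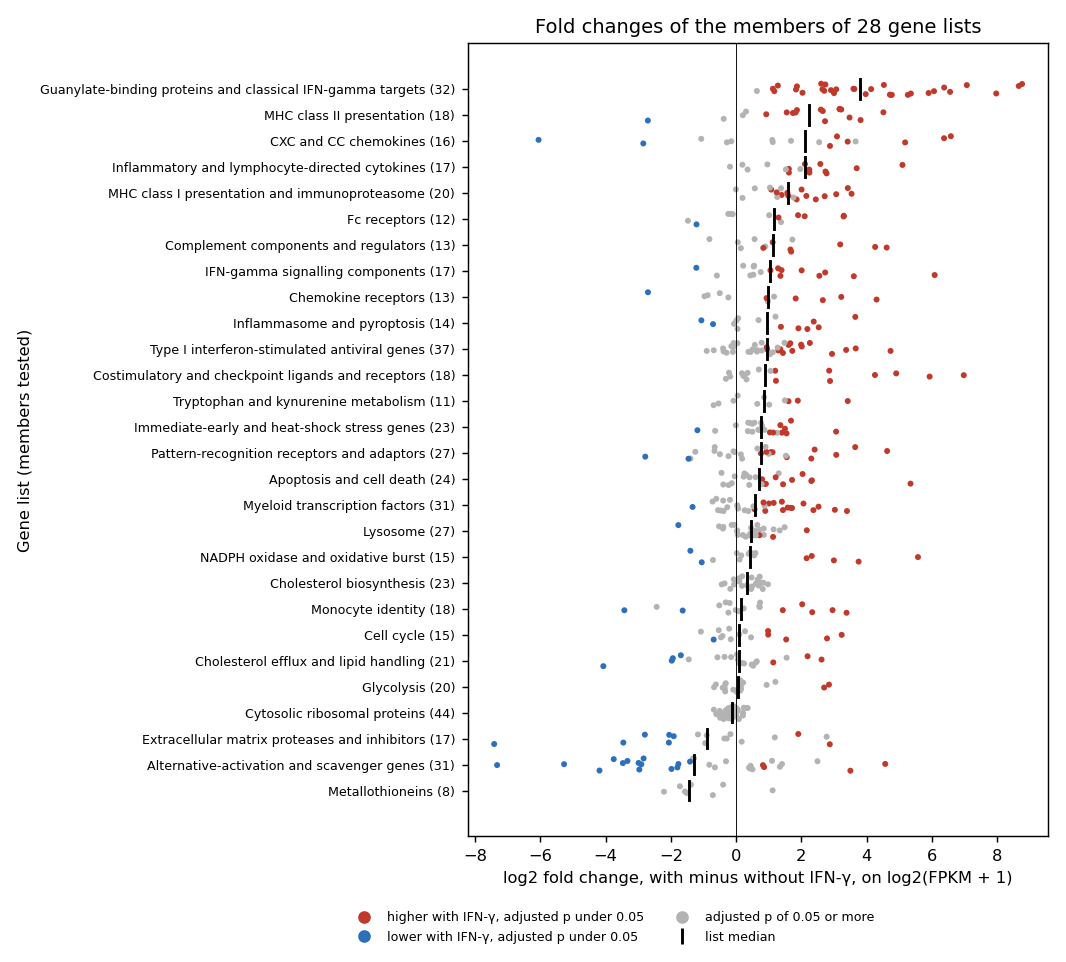
Log2 fold change (x axis, log2(FPKM + 1), with minus without IFN-γ) of each tested member of 28 gene lists (rows, number tested in parentheses), red if higher, blue if lower, grey if not past an adjusted p of 0.05, with a black bar at the median. Medians of cell cycle, glycolysis, monocyte identity and lipid handling genes, near 0 here, turned negative after rescaling to TPM.

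Of 16 CXC and CC chemokines tested, a list that left CXCL9 to the classical IFN-γ targets, 6 rose, 2 fell and 8 did not pass (limma camera adjusted p = 0.0177, 8.12e-06 to 0.529 over the alternatives, and adjusted p = 0.529 with an estimated correlation; 9 higher and 3 lower adjusted over the list alone). CXCL10 rose from 10.9 ± 5.63 to 1083 ± 184 FPKM, CCL8 from 0.745 ± 0.272 to 144 ± 19.8 FPKM and CXCL11, a ligand of CXCR3 like CXCL9 and CXCL10, from 0.730 ± 0.250 to 66.7 ± 37.1 FPKM. Besides PPBP, the neutrophil attractant CXCL5 fell by 2.85. The monocyte attractant CCL2 was at 116 ± 114 FPKM without and 1149 ± 584 FPKM with IFN-γ (adjusted p = 0.0514) and did not pass, nor did CXCL16 (log2 fold change 1.11, adjusted p = 0.091). The list itself was not past without IFNg- replicate 1 (adjusted p = 0.0851). CCL2 gained a call without IFNg- replicate 2 (adjusted p = 0.0159), without IFNg+ replicate 2 (adjusted p = 0.0496), after rescaling to TPM (adjusted p = 0.0495) and with a mean FPKM of at least 5 (adjusted p = 0.0486). CXCL16 gained a call without IFNg+ replicate 2 (adjusted p = 0.0101). Across the alternatives, adjusted p of CCL2 and CXCL16 ranged from 0.0101 to 0.635.

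Of 13 chemokine receptors, 5 rose, 1 fell and 7 did not pass, and the list was not past (limma camera adjusted p = 0.0888, 0.00217 to 0.592 over the alternatives, and adjusted p = 0.592 with an estimated correlation; 7 higher and 1 lower adjusted over the list alone), though it was after rescaling to TPM (adjusted p = 0.00217), after median alignment (adjusted p = 0.039) and without IFNg+ replicate 2 (adjusted p = 0.0103). The formyl peptide receptors FPR2 and FPR1 rose from 1.67 ± 0.971 to 50.8 ± 12.9 FPKM and from 12.6 ± 0.0245 to 128 ± 26.7 FPKM. CCRL2, CCR2 and CMKLR1 rose by 2.66, 1.83 and 0.93 on the log2 scale, and the fractalkine receptor CX3CR1 fell by 2.70. CCR1 and FPR3 did not pass (log2 fold changes 0.97 and -0.50). The threshold was missed by CCR2, CCRL2 and CMKLR1 without IFNg- replicate 1 (adjusted p from 0.0806 to 0.113), and by CCR2, CCRL2 and CMKLR1 without IFNg- replicate 2 (adjusted p from 0.0819 to 0.155). Significance was lost for CX3CR1 (adjusted p = 0.0977) without IFNg+ replicate 1, and for CX3CR1 (adjusted p = 0.0629) without IFNg+ replicate 2. The test was failed by CCR2 (adjusted p = 0.06) after rescaling to TPM, and by CCR2 (adjusted p = 0.0702) and CX3CR1 (adjusted p = 0.0555) after quantile normalization. No call remained for CCR2 (adjusted p = 0.0525) after median alignment. The adjusted p over all alternatives of these genes ranged from 0.00241 to 0.273.

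Of 17 inflammatory and lymphocyte-directed cytokines tested, 11 rose and 6 did not pass (limma camera adjusted p = 7.1e-07, 2.93e-10 to 0.348 over the alternatives, and adjusted p = 0.348 with an estimated correlation; 12 higher and 0 lower adjusted over the list alone). IL32 rose from 0.558 ± 0.258 to 56.8 ± 32.2 FPKM, the death ligand TNFSF10 (TRAIL) from 21.3 ± 9.06 to 298 ± 158 FPKM and the IL-12 family subunit IL27 from 0.231 ± 0.0200 to 7.44 ± 0.882 FPKM, while IL1B rose by 2.74 on the log2 scale. TGFB1 and IL18 did not pass (log2 fold changes 0.19 and -0.19). Of 18 costimulatory and checkpoint genes, 8 rose and 10 did not pass (limma camera adjusted p = 4.15e-05, 1.06e-06 to 0.385 over the alternatives, and adjusted p = 0.385 with an estimated correlation; 10 higher and 0 lower adjusted over the list alone). CD274, which encodes PD-L1, rose from 0.292 ± 0.000446 to 78.8 ± 16.9 FPKM, CD40 from 2.58 ± 0.184 to 107 ± 12.3 FPKM and PDCD1LG2, which encodes PD-L2, from 0.175 ± 0.0214 to 21.7 ± 4.83 FPKM. SIRPA and LGALS9 did not pass (log2 fold changes 0.35 and 0.32). 

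Of 13 complement genes tested, 7 rose and 6 did not pass (limma camera adjusted p = 0.000483, 1.3e-07 to 0.348 over the alternatives, and adjusted p = 0.348 with an estimated correlation; 8 higher and 0 lower adjusted over the list alone). Factor B, CFB, rose from 0.359 ± 0.0660 to 32.5 ± 5.14 FPKM, the classical pathway protease C2 from 5.55 ± 0.256 to 58.9 ± 1.36 FPKM, and C1QB from 6.79 ± 3.55 to 144 ± 43.8 FPKM. C1QA rose by 1.69 on the log2 scale, and CD46 and CFD did not pass (log2 fold changes 0.56 and 0.14). Of 12 Fc receptors, 5 rose, 1 fell and 6 did not pass, and the list was not past (limma camera adjusted p = 0.0709, 0.00276 to 0.385 over the alternatives, and adjusted p = 0.385 with an estimated correlation; 6 higher and 1 lower adjusted over the list alone), whereas it was after rescaling to TPM (adjusted p = 0.00276), after median alignment (adjusted p = 0.0307), without IFNg- replicate 1 (adjusted p = 0.0359), without IFNg- replicate 2 (adjusted p = 0.0431) and without IFNg+ replicate 2 (adjusted p = 0.00895). The high-affinity IgG receptor gene FCGR1A rose from 8.50 ± 3.97 to 88.5 ± 11.8 FPKM, and its near-copies FCGR1B and FCGR1C by 3.30 and 2.10; reads cannot be assigned among the 3 with certainty. FCER2 and FCER1G rose by 1.90 and 1.30, and FCGRT fell by 1.22. FCGR3A and FCGR2A did not pass (log2 fold changes -0.17 and -0.10). Calls were lost for FCER1G, FCER2, FCGR1C and FCGRT without IFNg- replicate 1 (adjusted p from 0.0638 to 0.0983), and for C1QA, FCER1G, FCER2, FCGR1C and FCGRT without IFNg- replicate 2 (adjusted p from 0.0554 to 0.114). The threshold was missed by C1QA (adjusted p = 0.081) without IFNg+ replicate 2, and by C1QA (adjusted p = 0.0538) after rescaling to TPM. Significance was lost for C1QA (adjusted p = 0.0656) and FCER1G (adjusted p = 0.0904) after quantile normalization. Over all alternatives, the adjusted p of these genes ranged from 0.00518 to 0.167.

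Of 15 NADPH oxidase and oxidative burst genes, 5 rose, 2 fell and 8 did not pass (limma camera adjusted p = 0.0302, 0.00369 to 0.364 over the alternatives, and adjusted p = 0.364 with an estimated correlation; 5 higher and 3 lower adjusted over the list alone). GCH1, which makes tetrahydrobiopterin, rose from 2.69 ± 0.415 to 175 ± 8.88 FPKM and the mitochondrial superoxide dismutase SOD2 from 54.4 ± 0.223 to 780.4 ± 316 FPKM. The oxidase subunit NCF1, whose reads are shared with pseudogenes, rose by 2.998 and the proton channel HVCN1 by 2.32 on the log2 scale. Haem oxygenase HMOX1 and catalase CAT fell by 1.06 and 1.40. The catalytic subunit CYBB did not pass (log2 fold change 0.59), nor did GPX1 (-0.71, adjusted p = 0.0564). The list was not past without IFNg- replicate 2 (adjusted p = 0.0621), without IFNg+ replicate 1 (adjusted p = 0.0682), with a mean FPKM of at least 5 (adjusted p = 0.0808) or after quantile normalization (adjusted p = 0.142). CAT was not past the threshold without IFNg- replicate 1 (adjusted p = 0.154) and without IFNg- replicate 2 (adjusted p = 0.0976). HMOX1 was not past the threshold without IFNg- replicate 1 (adjusted p = 0.0651), without IFNg- replicate 2 (adjusted p = 0.123) and without IFNg+ replicate 2 (adjusted p = 0.0655). GPX1 was past the threshold after rescaling to TPM (adjusted p = 0.0229), after quantile normalization (adjusted p = 0.0246), after median alignment (adjusted p = 0.0432), with a mean FPKM of at least 5 (adjusted p = 0.045) and without the variance trend (adjusted p = 0.0493). The adjusted p over all alternatives of these genes ranged from 0.00898 to 1.

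Of 27 pattern-recognition receptors and adaptors, 11 rose, 2 fell and 14 did not pass (limma camera adjusted p = 0.0334, 0.00107 to 0.364 over the alternatives, and adjusted p = 0.364 with an estimated correlation; 15 higher and 5 lower adjusted over the list alone). The lectin receptor genes CLEC6A, CLEC4E and CLEC4D rose from 0.0997 ± 0.0790 to 30.2 ± 21.7 FPKM, from 2.30 ± 0.682 to 45.6 ± 31.2 FPKM and from 0.730 ± 0.334 to 14.2 ± 6.70 FPKM. The endotoxin co-receptor CD14 fell by 1.46 and the lipid receptor TREM2 by 2.79. The DNA sensor IFI16 and the endotoxin receptor subunit LY96 did not pass (log2 fold changes 0.90 and -0.04). The list was not past without IFNg- replicate 2 (adjusted p = 0.0509) or with a mean FPKM of at least 5 (adjusted p = 0.0694). Of 14 inflammasome and pyroptosis genes, 6 rose, 2 fell and 6 did not pass (limma camera adjusted p = 0.0196, 0.000654 to 0.445 over the alternatives, and adjusted p = 0.445 with an estimated correlation; 7 higher and 2 lower adjusted over the list alone). The DNA sensor AIM2 rose from 0.446 ± 0.186 to 17.2 ± 2.58 FPKM and the inflammatory caspase CASP4 from 36.3 ± 2.11 to 171 ± 42.6 FPKM, while MEFV and P2RX7 rose by 2.53 and 2.38. NLRC4 and NLRP1 fell by 0.71 and 1.06, and PYCARD and CARD16 did not pass (log2 fold changes 0.04 and 0.69). The test was failed by CD14, NLRC4, NLRP1 and TREM2 without IFNg- replicate 1 (adjusted p from 0.08 to 0.141), and by CD14, CLEC4E, NLRC4, NLRP1 and TREM2 without IFNg- replicate 2 (adjusted p from 0.0547 to 0.131). No call remained for NLRC4 (adjusted p = 0.0741) and NLRP1 (adjusted p = 0.05) without IFNg+ replicate 1, and for NLRC4 (adjusted p = 0.101) without IFNg+ replicate 2. CARD16 gained a call without IFNg+ replicate 1 (adjusted p = 0.0493). IFI16 gained a call without IFNg+ replicate 1 (adjusted p = 0.0373). Across the alternatives, adjusted p of these genes ranged from 0.0018 to 1.

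Of 18 monocyte identity genes, 5 rose, 2 fell and 11 did not pass, and the list was not past (limma camera adjusted p = 0.408, 0.0611 to 0.785 over the alternatives, and adjusted p = 0.592 with an estimated correlation; 6 higher and 4 lower adjusted over the list alone). The alarmin S100A8 rose from 102 ± 19.5 to 1143 ± 578 FPKM and lysozyme, LYZ, from 1306 ± 399 to 6617 ± 2213 FPKM. S100A9 and LILRB3 rose by 2.03 and 1.43. The proteoglycan VCAN fell from 26.8 ± 10.9 to 1.51 ± 0.503 FPKM, and CSF1R, the receptor for macrophage growth factors, by 1.64. TYROBP and CST3 did not pass (log2 fold changes -0.24 and -0.20). The list's median of 0.16 turned to -0.19 after rescaling to TPM and to -0.11 after quantile normalization. LYZ was not past the threshold without IFNg- replicate 2 (adjusted p = 0.0592) and after quantile normalization (adjusted p = 0.105). TYROBP passed the test after quantile normalization (adjusted p = 0.035). Over all alternatives, the adjusted p of LYZ and TYROBP ranged from 0.00703 to 1. The control genes did not pass: ACTB was at 4275 ± 127 FPKM without and 5491 ± 1038 FPKM with IFN-γ (adjusted p = 0.263), and its log2 fold change of 0.35 turned to -0.01 after rescaling to TPM and -0.67 after quantile normalization. GAPDH was at 1034 ± 264 FPKM without and 831 ± 225 FPKM with IFN-γ (log2 fold change -0.32, adjusted p = 0.481).

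Markers of other blood cells were low in both groups. Of 14 T cell markers, 13 had a mean below 1 FPKM, as did 10 of 11 NK cell, 7 of 10 B cell, 8 of 12 dendritic cell, 11 of 14 granulocyte and 10 of 12 platelet and erythroid markers. Among those tested, CD28 fell from 5.66 ± 2.15 to 0.0122 ± 0.000380 FPKM (adjusted p = 0.00581), XCR1 from 2.63 ± 0.494 to 0.118 ± 0.0481 FPKM (adjusted p = 0.00705) and TREML1 from 2.13 ± 0.696 to 0.322 ± 0.330 FPKM (adjusted p = 0.0396). The single NK marker tested, NKG7, did not pass (log2 fold change 0.24), nor did the B cell markers CD22, CD79B and FCRLA (-0.20, -0.02 and -0.83). The same held for the dendritic cell markers CD1C, LILRA4 and ZBTB46 (0.17, 0.04 and 0.44) and haemoglobin HBB (-0.16). The granulocyte markers MPO, CLC and FCGR3B did not pass either (0.73, -0.02 and 0.43). FCGR3B was at 5.50 FPKM without and 7.98 FPKM with IFN-γ in the replicate 1 libraries. In the replicate 2 libraries it was at 0.401 and 0.845 FPKM. TREML1 lost the call without IFNg- replicate 1 (adjusted p = 0.135), without IFNg- replicate 2 (adjusted p = 0.0583) and without IFNg+ replicate 2 (adjusted p = 0.0732). Across the alternatives, adjusted p of TREML1 ranged from 0.0158 to 0.261.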

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

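Leaving out the 6 genes with a failed-fit flag was chosen after seeing the data and gave 1730 changed genes. All counts of changed genes kept their excess of rises over falls except under the 3 rescalings given with the main result. With no filter on low values, where 17789 genes share the adjustment, 1002 genes changed (550 higher, 452 lower, 663 by at least 2-fold) and 740 of the 1733 calls remained. With limma treat, which asks for more than a 1.5-fold change, 532 changed (347 higher, 185 lower, 532 by at least 2-fold). After rescaling to TPM, 2881 changed (2157 lower, 1708 by at least 2-fold), with the median of all genes at -0.309 and more genes tested. A pseudocount of 5, which shrinks low genes, left 662 genes with a 2-fold change, and a mean of at least 5 FPKM, which tests fewer genes, 405 lower genes. With an estimated correlation, camera had few degrees of freedom. There 0 of 20 lists stayed past and 0 of 28 had an unadjusted p under 0.05. Fry passed 15 lists: it lost 6 of the 20 and gained cell cycle (fry adjusted p = 0.0484). Each list's direction was the same. Leaving out 1 library, with the lone library assumed to vary like the others, gave 600 to 1389 changed, 364 to 905 higher, 236 to 484 lower and 600 to 1272 at least 2-fold changed genes. The lowest of each came from leaving out IFNg- replicate 1.

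The 2 groups shared part of their replicate deviations (below), which a block takes out of the residual spread and whose origin was not tested. The replicate number as a block gave 2582 changed genes, 1536 of them higher, and kept 1691 of the 1733 calls. With it, CD46, GPX1, IDI1, IFI16, IFITM3, MAF, MPO, MT2A, PDIA3 and PTPN6 passed (adjusted p from 0.0208 to 0.0489, MAF at 0.0226), C1QA, CCR2, FOSL1 and PLAUR did not (adjusted p from 0.0582 to 0.0702), the metallothioneins passed as a list (adjusted p = 0.0485) and tryptophan and kynurenine metabolism did not (adjusted p = 0.0549). The adjusted p of MAF over all alternatives ranged from 0.0226 to 0.519. Across genes, the replicate deviations of the 2 groups correlated (Pearson's r = 0.447), and still did at 0.442 after trends on transcript length and level were removed from the 9278 genes with a length (0.443 before), which argues against length as the cause. With 2 pairs, a shared donor and a shared library set-up were not told apart.

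Among 209 genes taken by the naming rule or by small counts, 92 of the 140 past the threshold kept their call under each alternative whose filter kept them. The other calls were lost mostly with no filter (45), with treat (37) or without an IFNg- library. Fewer were lost without an IFNg+ library or after quantile normalization (13), rescaling to TPM (10) or median alignment (5). The rest went with small RNA genes kept (7), pseudocounts of 0.1 (3) or 5 (5), the block (4) or no variance trend (1). MMP9, not past in the main test, passed at a log2 fold change of -2.20 without IFNg+ replicate 1 and reversed, to 1.48, without IFNg+ replicate 2, as its IFNg+ libraries lay at 184 and 13.4 FPKM. PSAP reversed under quantile normalization, to -0.913; the cause was not tested. Depth is unknown and each group has 2 libraries, so a gene that did not pass is not shown to be unchanged. In simulation 2% of 2-fold changes were recovered, but with fewer changed genes than here and so a stricter threshold.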

Other observations

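The tests of the PPBP, CD28 and scaling patterns below were chosen after the results they measure had been seen. In tryptophan and kynurenine metabolism, whose list left IDO1 to the classical IFN-γ targets, 3 of 11 genes tested rose and 8 did not pass (limma camera adjusted p = 0.0468, 0.00288 to 0.385 over the alternatives, and adjusted p = 0.385 with an estimated correlation; 6 higher and 1 lower adjusted over the list alone). IDO2 rose from 0.0181 ± 0.00449 to 9.99 ± 1.74 FPKM, NAMPT, which makes NAD precursors, from 27.9 ± 7.58 to 105 ± 13.3 FPKM, and KMO by 1.61 on the log2 scale, while SLC3A2 and CYP1B1 did not pass (log2 fold changes 0.05 and -0.54). The list was not past without IFNg+ replicate 1 (adjusted p = 0.19), after quantile normalization (adjusted p = 0.0518), with a pseudocount of 5 (adjusted p = 0.0655), with small RNA genes kept (adjusted p = 0.0502) or with no filter (adjusted p = 0.367, median 0.05). In apoptosis and cell death, 10 of 24 rose and 14 did not pass (limma camera adjusted p = 0.00047, 1.05e-05 to 0.348 over the alternatives, and adjusted p = 0.348 with an estimated correlation; 12 higher and 0 lower adjusted over the list alone); the anti-apoptotic BCL2A1 rose from 1.87 ± 0.116 to 123 ± 60.2 FPKM, and BIRC3 (2.32), FAS (2.31) and RIPK2 (2.04) followed by log2 fold change, while BID and TNFRSF1A did not pass (0.28 and -0.39). Of 31 myeloid transcription factors, 15 rose, 1 fell and 15 did not pass (limma camera adjusted p = 0.0123, 0.000113 to 0.506 over the alternatives, and adjusted p = 0.506 with an estimated correlation; 16 higher and 2 lower adjusted over the list alone; fry adjusted p = 0.0627). EGR2, MAFF, BATF3 and BHLHE40 rose by 3.40, 3.03, 2.53 and 2.37, CEBPD fell by 1.34, and SPI1 did not pass (0.04). Of 23 immediate-early and heat-shock genes, 8 rose, 1 fell and 14 did not pass (limma camera adjusted p = 0.000449, 3.19e-06 to 0.529 over the alternatives, and adjusted p = 0.529 with an estimated correlation; 12 higher and 2 lower adjusted over the list alone; fry adjusted p = 0.0994). ATF3 rose from 3.53 ± 1.31 to 38.03 ± 16.9 FPKM, with EGR3, HSPA8 and FOSL1 at 1.68, 1.55 and 1.497, FOS fell by 1.19, and JUNB and ZFP36 did not pass (0.50 and 0.42). Calls were lost for BATF3, BHLHE40, EGR3, FOS, FOSL1, HSPA8 and KMO without IFNg- replicate 1 (adjusted p from 0.0512 to 0.128), and for BHLHE40, EGR2, EGR3, FOS and KMO without IFNg- replicate 2 (adjusted p from 0.0524 to 0.109). The threshold was missed by EGR2 (adjusted p = 0.0847) and FOSL1 (adjusted p = 0.0961) without IFNg+ replicate 1, and by FOSL1 (adjusted p = 0.0569) after rescaling to TPM. Significance was lost for EGR2 (adjusted p = 0.0532) after quantile normalization, and for FOSL1 (adjusted p = 0.0514) after median alignment. TNFRSF1A passed the test after rescaling to TPM (adjusted p = 0.0296) and after quantile normalization (adjusted p = 0.0372). CYP1B1 passed the test without IFNg+ replicate 1 (adjusted p = 0.0167). Over all alternatives, the adjusted p of these genes ranged from 0.00239 to 1.

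Of 17 matrix proteases and inhibitors, 6 fell, 2 rose and 9 did not pass (limma camera adjusted p = 0.0274, 0.000155 to 0.529 over the alternatives, and adjusted p = 0.529 with an estimated correlation; 2 higher and 6 lower adjusted over the list alone). Besides THBS1, SERPINB2 and MMP19 fell from 23.1 ± 12.5 to 1.14 ± 0.903 FPKM and from 28.7 ± 12.8 to 3.24 ± 1.75 FPKM, and MMP25 and PLAUR rose by 2.87 and 1.91. MMP9 and TIMP2 did not pass (log2 fold changes -0.36 and -0.29). MMP9 was past the threshold in opposite directions without IFNg+ replicate 1 (log2 fold change -2.20, adjusted p = 0.00501) and without IFNg+ replicate 2 (log2 fold change 1.48, adjusted p = 0.0124), with an adjusted p of 0.00501 to 1 over all alternatives. The list's median of -0.90 was -0.14 without IFNg+ replicate 2, where the list was not past (adjusted p = 0.328). Nor was it past after rescaling to TPM (median -1.28, adjusted p = 0.439), quantile normalization (median -0.96, adjusted p = 0.0525) or median alignment (median -0.99, adjusted p = 0.07), with no filter (median -0.32, adjusted p = 0.0576) or with fry (adjusted p = 0.17). In lipid handling, 3 of 21 rose, 4 fell and 14 did not pass (limma camera adjusted p = 0.693, 0.147 to 0.916 over the alternatives, and adjusted p = 0.896 with an estimated correlation; 3 higher and 4 lower adjusted over the list alone), with a median of 0.08 but a mean and a test direction below 0, and a median of -0.24 after rescaling to TPM, -0.01 after quantile normalization and -0.01 after median alignment. FABP4 fell from 18.7 ± 0.546 to 0.176 ± 0.0960 FPKM, FABP5, CD9 and PLTP also fell (log2 fold changes -1.97, -1.94 and -1.695), and NR1H3, ACSL1 and SOAT1 rose by 2.62, 2.19 and 1.14. LIPA and NPC2 did not pass (0.61 and -0.15). Of 27 lysosome genes, 3 rose, 1 fell and 23 did not pass (limma camera adjusted p = 0.0274, 0.000956 to 0.592 over the alternatives, and adjusted p = 0.592 with an estimated correlation; 9 higher and 2 lower adjusted over the list alone; fry adjusted p = 0.185), and the list was not past without IFNg- replicate 2 (adjusted p = 0.0621), without IFNg+ replicate 1 (adjusted p = 0.273) or after quantile normalization (adjusted p = 0.305). CTSH, CD63 and GRN rose by 2.17, 1.13 and 0.72, ATP6V0D2 fell by 1.77, and CTSB and PSAP did not pass (0.29 and 0.21). The test was failed by CD63, CD9, GRN, NR1H3, PLAUR and SOAT1 without IFNg- replicate 1 (adjusted p from 0.0676 to 0.192), and by CD63, CD9, GRN, NR1H3 and SOAT1 without IFNg- replicate 2 (adjusted p from 0.1 to 0.204). No call remained for GRN, PLAUR and SOAT1 without IFNg+ replicate 1 (adjusted p from 0.0837 to 0.103), and for GRN (adjusted p = 0.0578) without IFNg+ replicate 2. Calls were lost for GRN, PLAUR and SOAT1 after rescaling to TPM (adjusted p from 0.0526 to 0.156), and for GRN, PLAUR and SOAT1 after quantile normalization (adjusted p from 0.053 to 0.128). The threshold was missed by GRN (adjusted p = 0.0588) and PLAUR (adjusted p = 0.0506) after median alignment. Across the alternatives, adjusted p of these genes ranged from 0.00318 to 1.

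Of 15 cell cycle genes, 5 rose, 1 fell and 9 did not pass (limma camera adjusted p = 0.507, 0.0484 to 0.872 over the alternatives, and adjusted p = 0.692 with an estimated correlation; 6 higher and 3 lower adjusted over the list alone; fry adjusted p = 0.0484), and the median of 0.10 turned to -0.39 after rescaling to TPM and -0.10 after quantile normalization. The cyclin CCND1 rose from 0.122 ± 0.0932 to 9.65 ± 1.93 FPKM and the cell cycle inhibitor CDKN1A from 33.3 ± 7.66 to 243 ± 96.5 FPKM. CCND2, CCND3 and PCNA rose by 1.54, 0.98 and 0.98, MCM7 fell by 0.69, and CDKN1B and MCM5 did not pass (0.10 and -0.53). In glycolysis, 2 of 20 rose and 18 did not pass (limma camera adjusted p = 0.815, 0.0732 to 0.96 over the alternatives, and adjusted p = 0.94 with an estimated correlation; 2 higher and 0 lower adjusted over the list alone), with a median of 0.07 that turned to -0.23, -0.22 and -0.03 after rescaling to TPM, quantile normalization and median alignment. SLC2A3 and HK2 rose by 2.85 and 2.70, and PKM2 did not pass (-0.09). None of 23 cholesterol biosynthesis genes passed (limma camera adjusted p = 0.0728, 0.00539 to 0.592 over the alternatives, and adjusted p = 0.592 with an estimated correlation), with IDI1 and INSIG1 at 0.69 and 0.61; 0 passed adjusted over the list alone and 8 had an unadjusted p under 0.05. That list was past without IFNg+ replicate 2 (median 0.43, adjusted p = 0.00539) and with no filter (adjusted p = 0.0266). None of 44 cytosolic ribosomal protein genes passed, although their list was lower (median -0.14, and -0.50 after rescaling to TPM, -0.45 after quantile normalization, -0.24 after median alignment and -0.06 without IFNg+ replicate 1; limma camera adjusted p = 0.0177, 1.94e-06 to 0.634 over the alternatives, and adjusted p = 0.634 with an estimated correlation; fry adjusted p = 0.292; adjusted p = 0.231 without IFNg+ replicate 1); 4 had an unadjusted p under 0.05, and RPLP1 was at -0.34. None of 8 metallothioneins, whose copies share reads, passed (limma camera adjusted p = 0.179, 0.000112 to 0.976 over the alternatives, and adjusted p = 0.701 with an estimated correlation), with MT2A at 504 ± 59.1 FPKM without and 1127 ± 396 FPKM with IFN-γ and MT1X at 308 ± 112 FPKM without and 121 ± 116 FPKM with IFN-γ; 1 had an unadjusted p under 0.05, and the list's median of -1.45 was -2.81 without IFNg+ replicate 1, where it was past (adjusted p = 0.000112), and 0.04 without IFNg+ replicate 2. Significance was lost for CCND3, MCM7, PCNA and SLC2A3 without IFNg- replicate 1 (adjusted p from 0.0908 to 0.142), and for CCND3, MCM7, PCNA and SLC2A3 without IFNg- replicate 2 (adjusted p from 0.0591 to 0.172). The test was failed by MCM7 (adjusted p = 0.153) and PCNA (adjusted p = 0.0659) without IFNg+ replicate 1, and by CCND3 (adjusted p = 0.0657) and MCM7 (adjusted p = 0.0642) without IFNg+ replicate 2. No call remained for CCND3 (adjusted p = 0.0523) and PCNA (adjusted p = 0.0507) after rescaling to TPM, and for PCNA (adjusted p = 0.0506) after quantile normalization. The threshold was passed by MT1X (adjusted p = 0.0103) without IFNg+ replicate 1, and by MT2A (adjusted p = 0.013) without IFNg+ replicate 2. Calls were gained for MCM5 (adjusted p = 0.0444) after rescaling to TPM. Over all alternatives, the adjusted p of these genes ranged from 0.00267 to 1.

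PPBP, known as an abundant platelet transcript, was at 120.1 and 44.4 FPKM in the IFNg- libraries and 0.183 and 0.0477 FPKM in the IFNg+ libraries. Platelet RNA in the IFNg- libraries would bring the other abundant platelet transcripts too, and TREML1, a marker of the fixed platelet list, fell with it from 2.13 to 0.322 FPKM (adjusted p = 0.0396, but 0.135 without IFNg- replicate 1, 0.0583 without IFNg- replicate 2 and 0.0732 without IFNg+ replicate 2, and 0.0158 to 0.261 over all alternatives). The median of PF4, ITGA2B, GP9, GP1BA and TUBB1 was at most 0.413% of PPBP there, PF4 being highest of them at 0.326 FPKM on average, which argues against platelets as the source. The log2 fold change of PPBP was -6.06, and -6.22 after quantile normalization and -6.15 after median alignment; it was -7.53 after rescaling to TPM, where the pseudocount of 1 is smaller beside the values. A candidate explanation that stays open is transcription of PPBP by the cultured cells themselves that is lower with IFN-γ, which these data do not test.

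CD28, a T cell costimulatory receptor, was at 5.66 FPKM without IFN-γ and 0.0122 FPKM with it. T cells in the IFNg- libraries would bring CD3 transcripts. The median of CD3D, CD3E, CD3G, CD2 and LCK was at most 2.31% of CD28 in these libraries, with CD3D the highest at 0.228 FPKM, which argues against T cells as the source. How the monocytes were isolated is not given in the sources used here. Which cells in the culture expressed CD28, the monocytes or others, was not tested.

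More genes rose than fell with the deposited FPKM. The scale of the FPKM between libraries may account for this excess, and whether the authors scaled across libraries is not stated. Quantile normalization and median alignment cannot decide it, since both centre the libraries on each other and so pull the balance towards even in advance. On the same 10223 genes, the share of higher genes among the calls was 49.3% after the first and 48.1% after the second. It was 25.1% after rescaling to TPM, which also tested 11471 genes and made the pseudocount of 1 smaller beside the values. A real excess of rises with IFN-γ stays open, because no spike-in or count fixes the scale. Of the 1733 calls, 1394 remained after rescaling to TPM, 1407 after quantile normalization and 1559 after median alignment.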
